A study of Homo sapiens with 2 samples.

How the data were processed

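The series holds 2 RNA sequencing libraries of human prostate cancer cells, 1 labelled ENZ and 1 labelled ENZ-con. Per the labels' protocols, total RNA was extracted with Trizol, mRNA was isolated, and directional libraries were made by the dUTP method from fragmented mRNA, amplified by PCR and sequenced as paired reads of 150 bases. The submitters' processing notes name fastp 0.23.4, featureCounts 2.0.6, edgeR 4.0.16 and the hg38 build, with no role or order, and the aligner and the annotation release are not given in the sources used here. Whether counting used strand is not given either, so overlapping and antisense genes can have exchanged reads. The library protocol names no molecular identifiers.

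The deposited table gives raw counts per protein-coding gene, which the authors made and did not normalize, per the file headers and the values, whole numbers with different totals in each library. The authors' CPM values, per the file headers, equal the count divided by 1 constant per library, 13.2 for ENZ and 14.3 for ENZ-con where the count totals in the same unit are 13.5 and 13.9. The constants thus differ from the totals, as after some scaling of library size. Scaling by the trimmed mean of M-values (TMM), as used below, gave effective sizes of 13277764 counts for ENZ and 14137775 for ENZ-con. These are near the authors' constants but do not reproduce them. The authors' deposited FPKM values are fragments per kilobase scaled by library size, per the file headers. For 14569 genes with counts in both libraries, the ratio of count to FPKM in ENZ over that in ENZ-con had a median of 0.966. The table has 16644 rows, in which 4 gene IDs stand on 2 rows with equal values and were counted once, leaving 16640. Of these, 593 had 0 counts in both libraries, 16637 were found in GENCODE release 29, and 16596 had a current symbol. Coordinates are those of GENCODE release 29 on GRCh38, the assembly that hg38 denotes.

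All comparisons started from the counts. With 1 library per group there is no estimate of variation between cultures, so no test was made and no p-value is given, and the comparison is of these 2 libraries, not of the conditions. Library sizes were scaled by TMM in edgeR 4.0.16 under R 4.3.3. Log2 fold changes of ENZ over ENZ-con carry a prior count of 2, which draws low-count genes towards 0, whereas folds are plain ratios of scaled counts. Each ratio has an exact 95% interval (Clopper-Pearson, on the count in ENZ given the sum of both), computed with scipy 1.17.1. A count of 0 allows up to 0.226 TMM-scaled CPM in ENZ and 0.212 in ENZ-con at a floor of 3 counts per library, and folds against a count of 0 are lower bounds at that floor. Genes with 1 to 3 counts in a library have a ratio with its counting interval. A gene was called higher or lower when its ratio was at least 2 in either direction, its interval excluded 1, and its CPM was at least 1 in at least 1 library.

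The rule, the alternatives and 46 gene lists with 1052 symbols, 1009 of them matched, were fixed before the data were examined. For each list the median log2 fold change over members with a CPM of at least 1 was set against the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list stood apart when its median fell in the lowest or highest 2.5% and it had at least 5 members. This describes the 2 libraries and is not a test of the conditions. Some genes are in more than 1 list. Genes named in the text follow a rule. They are the 12 higher and the 12 lower genes whose interval bound nearest to no change lay farthest from it, leaving out clone-based names and sex-specific genes. Added to these were up to 4 higher and 4 lower members of each list that stood apart and of the lists for androgen-responsive genes, steroid receptors, m6A, PI3K-AKT-mTOR and neuroendocrine genes. WTAP, USP7, AKT1, AKT2 and KLK3 are named in any case, some further genes of this rule are not reported here, and other genes are said to have been chosen after their values were seen.

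The rule was tested on simulated counts for this comparison, drawn for 12594 genes from the real means and library sizes with 200 genes changed. With counting error alone, 49 of 50 genes changed 3-fold were recovered, and 50 of 50 at each of 4-fold, 8-fold and 16-fold, while 42 of 12394 unchanged genes passed the rule. With a coefficient of variation of 0.2 between cultures, 44 of 50 were recovered at 3-fold, 48 of 50 at 4-fold and 50 of 50 at 8-fold and 16-fold. The list percentile was tested on independent normal values in place of counts, with fewer random lists than in the comparison. Of 400 random lists of 20 genes with no shift 23 stood apart. Of 100 lists shifted by 1 standard deviation 97 did. Genes of a real list can vary together, which these values did not include.

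Alternatives fixed beforehand were DESeq2 1.42.0 size factors, total counts, no CPM minimum, a CPM minimum of 5, other fold limits, a 99% interval, intervals widened by an assumed coefficient of variation, a prior count of 0.5, means in place of medians, and the authors' CPM for named genes. Chosen after seeing the data were scaling without mitochondrially encoded genes, removal of smooth trends on GC content and transcript length (lowess with a span of 0.3, statsmodels 0.14.6), and the authors' CPM for the gene counts. GC content and length were found for 12574 of the 12594 genes. Pathway labels in the deposited table were used for a description that was also chosen after seeing the data, and its gene ontology labels were not used here.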

Results

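RNA sequencing libraries were made from poly(A)-selected RNA of human prostate cancer cells. The series describes C4-2B cells, an androgen-independent line of the LNCaP lineage, that were kept in medium with 20 µM enzalutamide for over 4 months to obtain a resistant derivative. Enzalutamide is an antiandrogen used against prostate cancer. There were 2 libraries, labelled ENZ and ENZ-con, with 1 library per group, so no difference below has a replicate check. The labels do not state whether ENZ is the resistant derivative or cells exposed for a shorter time, nor which cells ENZ-con is, and the groups are therefore called by their labels. The ENZ library held 13470930 counts and the ENZ-con library 13935047, over 16640 protein-coding gene IDs. At least 1 count was found for 15325 genes in ENZ and for 15291 in ENZ-con. A gene is called higher or lower in ENZ where its scaled ratio was at least 2 in either direction, its 95% counting interval excluded no change, and its CPM, the count scaled by library size, reached 1 in at least 1 library. Brackets give log2 counting intervals (exact, Clopper-Pearson), which cover counting error only and no variation between cultures. PCR reads without molecular identifiers are not independent molecules, so the intervals can be too narrow for counting error too.

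The comparison of ENZ with ENZ-con asks how the transcriptomes of the libraries labelled ENZ and ENZ-con differ. A joint list of glycolytic enzyme and hypoxia-response mRNAs was higher in the ENZ library, with a median log2 fold change of 1.94. Mitochondrially encoded mRNAs were lower, with a median of -1.78. Genes of DNA replication and mitosis were lower together, with medians of -1.81 and -1.61. Many androgen-responsive genes were lower, with a median of -1.40. Lists of p53 and FOXO targets, of the unfolded protein response and of the amino acid response through ATF4 stood apart as higher, while heat shock proteins and NRF2 targets did not stand apart.

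Of 12594 genes with a CPM of at least 1 in at least 1 library, 1524 were higher and 1729 lower in ENZ, together 25.8%. A 4-fold limit left 364 higher and 416 lower. The median log2 fold change over the 12594 genes was -0.02. Of 46 gene lists, 22 stood apart from random lists matched on expression, 14 of them higher and 8 lower. Among the 44 lists with at least 5 measured members, 2.2 would do so if genes varied independently. Genes of a list can vary together between 2 cultures, and some lists share genes, so this number does not measure chance here. In simulated libraries with no change in a gene beyond a coefficient of variation of 0.2 between cultures, 312 of 12394 genes passed the rule. With a coefficient of 0.4, 2964 passed, so the counts of genes depend on a variation that 1 library per group does not measure.

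**Figure D1:**
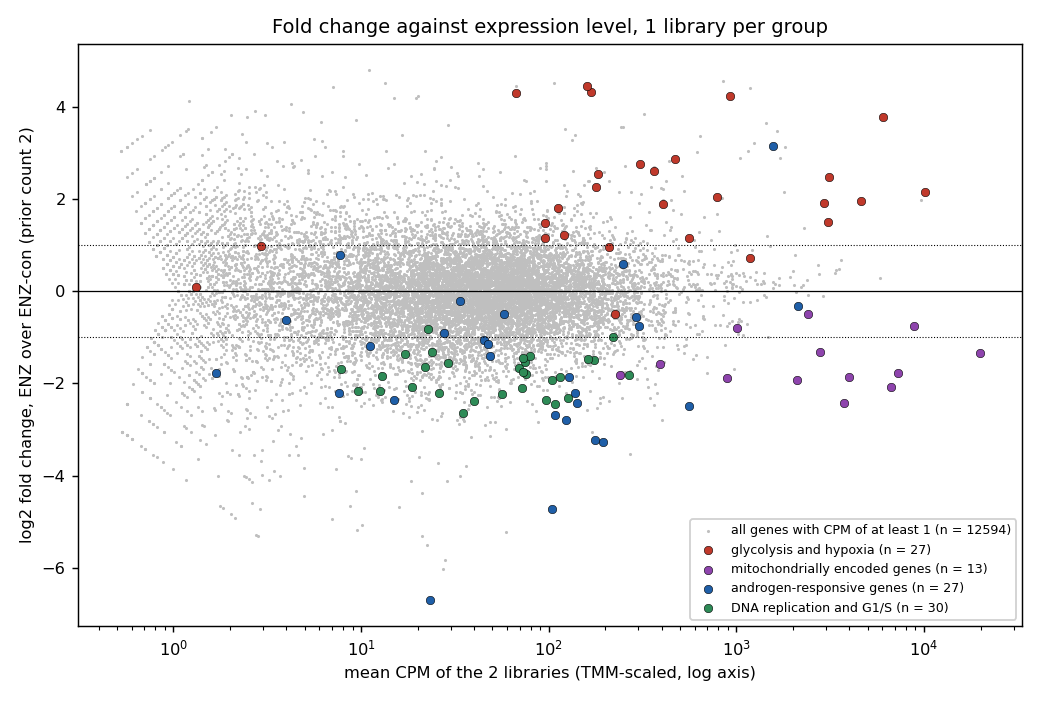
Log2 fold change of ENZ over ENZ-con (vertical axis, prior count of 2) against the mean TMM-scaled CPM of both libraries (horizontal log axis) for 12594 genes, each a point, with 4 gene lists coloured and dotted lines at 2-fold. The glycolysis and hypoxia list lies mostly above the upper line, and the lists for mitochondrially encoded genes, DNA replication and androgen-responsive genes mostly below 0.

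The genes named in the series title differed little at the mRNA level. WTAP, which encodes a subunit of the N6-methyladenosine (m6A) RNA methyltransferase complex, had 735 counts in ENZ and 1138 in ENZ-con, a log2 fold change of -0.54 (-0.68 to -0.41). WTAP (ENSG00000146457) lies on the plus strand of chromosome 6, from 159725585 to 159756319 in GRCh38. USP7, a deubiquitinating enzyme gene on chromosome 16 from 8892094 to 8964514, stood at -0.25 (-0.34 to -0.16). The kinase gene AKT1 was at -0.16 (-0.21 to -0.10) and AKT2 at 0.25 (0.17 to 0.34). None of these 4 genes reached the 2-fold rule. Among 20 measured m6A writers, erasers and readers, 3 were higher and 0 lower. The median of 0.15 did not stand apart and was 0.06 with trends on GC content and length removed. The 3 higher genes were the reader IGF2BP2 at 1.75 (1.31 to 2.31), the demethylase ALKBH5 at 1.32 (1.26 to 1.37) and the nuclear reader YTHDC1 at 1.45 (1.05 to 1.92). Of 44 measured ubiquitin-specific proteases, 4 were higher and 2 lower, with a median of 0.19 that did not stand apart either. The list did so without a CPM minimum and with a minimum of 5, but its mean was 0.08.

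The PI3K-AKT-mTOR list did not stand apart, with a median of 0.20 over 31 members, 2 higher and 6 lower, although it stood apart as higher without a CPM minimum, and its mean was -0.04. Its lower members included INPP4B, a phosphoinositide phosphatase gene, at -2.17 (-2.81 to -1.69), and SGK1, a kinase related to AKT, at -2.05 (-2.72 to -1.56). IGF1R, a receptor upstream of the pathway, was lower at -1.57 (-1.67 to -1.47), and PIK3R1, a regulatory subunit of PI3K, at -1.40 (-1.67 to -1.16). The inhibitor gene PIK3IP1 was higher at 1.77 (1.51 to 2.05), as was RICTOR, a component of mTOR complex 2, at 1.08 (0.90 to 1.27). Target genes of the FOXO transcription factors, which AKT phosphorylates and keeps out of the nucleus, stood apart with a median of 0.99, above all 10000 random lists. Of 19 measured FOXO targets 9 were higher and 0 lower, led by TXNIP at 2.89 (2.85 to 2.93) and the ubiquitin ligase gene FBXO32 at 2.00 (1.66 to 2.43). PIK3IP1 is in this list as well as in the PI3K-AKT-mTOR list, and GADD45A is also a p53 target, so these lists are not separate.

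Androgen-responsive genes were lower as a group, below all 10000 random lists, with 17 of 27 members lower and 1 higher. MAF, a transcription factor gene, had 4 counts in ENZ and 651 in ENZ-con, which is 153-fold lower, with a log2 fold change of -6.69 (-9.14 to -5.89). C1orf116 was lower at -4.74 (-5.07 to -4.47). FKBP5, a co-chaperone of steroid receptors, was 9.77-fold lower at -3.28 (-3.43 to -3.15), and SLC45A3, a prostate-enriched transporter gene, 9.48-fold lower at -3.24 (-3.39 to -3.10). NDRG1, which is induced by hypoxia as well as by androgen, was the member that was higher, at 3.15 (3.11 to 3.20). KLK3, the gene for prostate-specific antigen, was abundant in both libraries, with 1890 CPM in ENZ and 2378 in ENZ-con, a log2 fold change of -0.33 (-0.35 to -0.31). The list of steroid receptors and cofactors did not stand apart, with a median of -0.18 over 15 members. Its 2 higher members were GATA2, a transcription factor gene of the luminal lineage, at 1.97 (1.90 to 2.04), and NR3C1, the glucocorticoid receptor gene, at 1.71 (1.19 to 2.41).

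Genes of androgen synthesis and inactivation stood apart as lower, with a median of -0.72 over 17 members, although 4 were higher and 7 lower. The lower members were led by UDP-glucuronosyltransferases, which inactivate androgens by conjugation. UGT2B28 had 0 counts in ENZ and 80 in ENZ-con, at least 25-fold lower against a floor of 3 counts per library, and the list median was -0.72 with this gene at its bound. UGT2B11 was lower at -3.41 (-4.22 to -2.89), UGT2B15 had 2 counts against 40 (-7.33 to -2.28) and UGT2B17 was at -2.59 (-3.67 to -1.93). Higher members were AKR1C3, which makes testosterone from androstenedione, with 46 counts against 4 at 3.07 (2.16 to 5.55), and SRD5A3 at 1.30 (1.19 to 1.42). The UGT2B genes resemble one another closely, as do the AKR1C genes, so the split of reads within either family is uncertain. With a CPM minimum of 5 the median was -0.72 too, but at percentile 2.58 the list no longer stood apart.

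Glycolysis and hypoxia genes formed the list with the highest median, above all 10000 random lists, with 23 of 27 members higher and 0 lower. This list joins glycolytic enzymes with other hypoxia genes, so its median is not that of glycolysis alone. The glycolysis and gluconeogenesis pathway label, examined after the data were seen, had a median of 0.24 over 45 members. Of these 15 were higher and 5 lower, at percentile 96.1. ANKRD37, a target of hypoxia-inducible factor, was 22.2-fold higher, a log2 fold change of 4.46 (4.26 to 4.68). P4HA1, a prolyl hydroxylase subunit of collagen synthesis, was higher at 4.24 (4.16 to 4.32), and CA9, the carbonic anhydrase typical of hypoxic cells, at 4.29 (4.01 to 4.64). GPI, the second enzyme of glycolysis, was at 11234 CPM in ENZ and 817 in ENZ-con, a log2 fold change of 3.78 (3.75 to 3.81). ALDOA, the aldolase gene, was higher at 4.32 (4.14 to 4.54), but the table holds a second, overlapping ALDOA entry with 62 and 29 counts, so its size is uncertain. LDHA, which makes lactate from pyruvate, was higher at 1.91 (1.89 to 1.94). VEGFA, a hypoxia-induced angiogenic factor, was higher at 3.47 (3.42 to 3.51), and ERO1A, an oxidase of disulfide formation in the endoplasmic reticulum, at 4.55 (4.46 to 4.64).

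Mitochondrially encoded genes took 3.18% of the counts in ENZ (exact binomial 95% interval 3.17% to 3.19%) and 8.92% in ENZ-con (8.90% to 8.93%). This share, which also varies with RNA quality and handling, differed alongside each gene group described here. Of 13 such genes 10 were lower and 0 higher, below all 10000 random lists. MT-CYB, a complex III subunit, was lower at -2.43 (-2.46 to -2.41), and MT-CO3, a complex IV subunit, at -2.07 (-2.09 to -2.06). Nuclear genes of oxidative phosphorylation shifted less, with a median of -0.40 over 31 members. That list stood apart as lower although only ATP5MC1, an ATP synthase subunit gene, passed the rule, at -1.12, and it no longer stood apart once trends on GC content and length were removed, with a median of -0.23. Ribosomal protein genes did not stand apart, with a median of 0.21 and 0 of 34 members past the rule.

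Genes of cell division were lower nearly throughout. Of 30 DNA replication and G1/S genes 28 were lower and 0 higher, and of 29 mitotic genes 27 were lower and 0 higher, both lists below all 10000 random lists. The replication initiation gene MCM10 was lower at -2.63 (-2.93 to -2.38), and MCM2, a subunit of the replicative helicase, at -2.46 (-2.61 to -2.32). The kinetochore gene NDC80 was lower at -2.37 (-2.56 to -2.21) and CCNB1, encoding cyclin B1, at -2.31 (-2.42 to -2.21). DNA repair genes had a median of -1.13, with 14 of 23 lower, among them XRCC2 at -2.52 (-2.91 to -2.20) and BRCA2 at -1.86 (-2.16 to -1.60). MYC target genes had a median of -1.34, with 14 of 22 lower and 2 higher, including the nucleolar protein genes NOP16 at -2.83 (-3.09 to -2.61) and NOP56 at -2.29 (-2.40 to -2.19). MYC itself was lower at -1.86 (-2.05 to -1.68).

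In the list of cyclins, cyclin-dependent kinases and their inhibitors, with a median of 0.73 over 17 members, 6 were higher and 3 lower. CDKN1A, encoding p21, was higher at 2.39 (2.32 to 2.46), CDKN2B at 2.15 (1.47 to 3.20), CDKN1B at 1.56 (1.43 to 1.70) and RBL2, a retinoblastoma-family gene, at 1.70 (1.59 to 1.82). CDK4 was lower at -1.34 (-1.44 to -1.24), CDK2 at -1.07 and RBL1, of the same family as RBL2, at -1.13 (-1.40 to -0.88). Targets of p53 had a median of 0.84, with 11 of 24 higher and 0 lower, led by GDF15, a stress-induced cytokine, at 4.40 (4.33 to 4.48) and the pro-apoptotic gene BBC3 at 3.05 (2.71 to 3.48). Replication-dependent histone genes stood apart as higher, with a median of 1.10 over 13 members, 9 higher and 1 lower. HIST1H4H was higher at 2.72 (2.62 to 2.82) and HIST1H2BD at 2.58 (2.39 to 2.81), where near-identical family members can share reads.

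**Figure D2:**
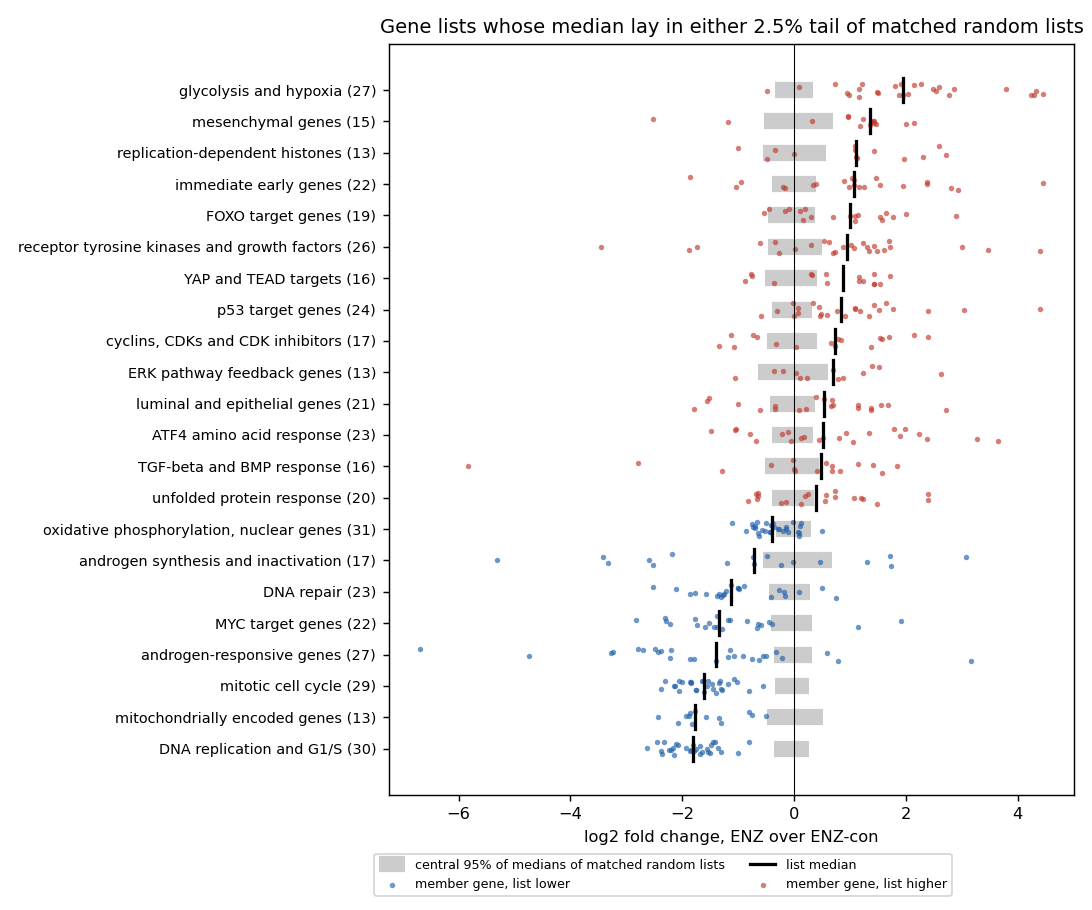
Log2 fold change of ENZ over ENZ-con (horizontal axis) for the measured members of the 22 gene lists that stood apart, with list medians as black bars, grey bands for the central 95% of medians of matched random lists, and member numbers in brackets. Medians run from -1.81 for DNA replication and G1/S to 1.94 for glycolysis and hypoxia, and UGT2B28, with 0 counts in ENZ, is drawn at its fitted value.

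Stress-response genes were higher in part. The list for the amino acid response through ATF4 had a median of 0.51 over 23 members, 9 higher and 3 lower. DDIT4, an inhibitor of mTOR complex 1, was higher at 3.65 (3.59 to 3.70) and DDIT3, the transcription factor CHOP, at 3.27 (3.12 to 3.44), while the serine synthesis genes PSPH and PHGDH were lower at -1.49 and -1.05. Pathway labels, examined after the data were seen, went the other way in part. Aminoacyl-tRNA biosynthesis had a median of -0.41 over 43 members, 1 higher and 11 lower. Glycine, serine and threonine metabolism had a median of -0.72 over 32 members, 4 higher and 11 lower. Both lay in the lowest 2.5% of matched random lists. Genes past the rule in the aminoacyl-tRNA pathway included VARS, whose counts are unreliable as given below. Others, chosen after their values were seen, were mitochondrial synthetase genes such as MARS2 and LARS2, and also FARSA and FARSB, which are not mitochondrial. That pathway therefore does not isolate ATF4 targets. The unfolded protein response list had a median of 0.40, with 6 of 20 higher and 0 lower, including the stress sensor gene ERN1 at 2.39 (2.25 to 2.55) and DNAJB9 at 2.40 (2.24 to 2.58). Immediate early genes, which respond to growth factors and to handling of cells, had a median of 1.07, with 13 of 22 higher and 3 lower. FOS was higher at 4.44 (4.16 to 4.82) and JUND at 2.81 (2.74 to 2.89).

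Growth factor and receptor genes had a median of 0.94, with 11 of 26 higher and 3 lower. EGFR was higher at 3.01 (2.94 to 3.08) and AXL, another receptor tyrosine kinase gene, at 1.43 (1.22 to 1.65), whereas the ligand gene IGF1 was lower at -3.46 (-5.55 to -2.61), and the receptor genes EPHA3 and PDGFRB at -1.73 (-2.16 to -1.38) and -1.88 (-3.57 to -0.95). Feedback genes of the ERK pathway had a median of 0.69, with 4 of 13 higher and 1 lower, among them ETV4 at 2.63 (1.89 to 3.98) and DUSP6 at 1.53 (1.16 to 1.96), and the list no longer stood apart without a CPM minimum, with a median of 0.46. Targets of YAP and TEAD had a median of 0.87, with 8 of 16 higher and 0 lower, including F3 at 1.71 (1.38 to 2.10) and ANKRD1 at 1.43 (1.18 to 1.71). The TGF-beta and BMP list had a median of 0.49 but a mean of -0.08, and it stood apart by its median alone. BMPR1B, a BMP receptor gene, was far lower at -5.83 (-7.07 to -5.21), and without it the mean was 0.31. ID2 was higher at 1.83 (1.71 to 1.95) and PMEPA1, which also responds to androgen, lower at -2.79 (-2.95 to -2.65), and with trends on GC content and length removed the list median was 0.40, at percentile 95.6 and no longer apart.

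Mesenchymal genes had a median of 1.36, above all 10000 random lists, with 11 of 15 higher and 2 lower, and a mean of 0.90. Fibronectin FN1 was higher at 2.15 (2.07 to 2.24), CDH11 at 2.00 (1.25 to 3.22) and vimentin VIM at 1.36, while the transcription factor gene SNAI2 was lower at -2.52 (-3.27 to -2.01). Of 7 measured fibroblast genes 3 were higher and 1 lower, with a median of 0.54 that did not stand apart. Their median was 0.94 with a CPM minimum of 5, and their mean was 0.33. Luminal and epithelial genes also stood apart as higher, with a median of 0.53 over 21 members, 7 higher and 4 lower, though not by their mean of 0.34. ELF3, an epithelial transcription factor gene, was higher at 2.72 (2.56 to 2.89) and the tight junction gene CLDN4 at 1.68 (1.63 to 1.74), while the surface glycoprotein gene CD24 was lower at -1.57 (-1.77 to -1.38). In the neuroendocrine list 4 of 8 measured members were higher and 0 lower, with a median of 0.65 that did not stand apart. Its mean of 1.20 did, but the median was 0.26 without a CPM minimum and 0.02 with a minimum of 5. Its member ENO2 is also a glycolytic enzyme and was higher at 3.37 (3.30 to 3.45), and NCAM1 had 30 counts against 1 (2.41 to 10.35). Markers of leukocytes and endothelial cells had 2 measured members each, of which 2 and 1 were lower, with medians of -2.01 and -1.08, too few members to set against random lists. Without a CPM minimum these medians were -0.47 and 0.28.

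Outside these lists, the 12 genes farthest above and the 12 farthest below no change by their intervals included further secreted and signalling genes. IGFBP5 and IGFBP3, which bind insulin-like growth factors, were higher at 4.78 (4.13 to 6.21) and 4.51 (4.27 to 4.80), and PREX1, an exchange factor for Rac, at 4.52 (3.94 to 5.60). PTGFR, the prostaglandin F receptor gene, was 79.2-fold lower, with 9 counts against 759. KCNH8, a potassium channel gene, was lower at -5.22 (-5.79 to -4.84), ST6GALNAC1, a sialyltransferase gene, at -5.30 (-6.48 to -4.70) and ZNF385B at -5.51 (-6.75 to -4.89). TUBA3D had 6 counts against 281, but alpha-tubulin genes resemble one another and its reads could be shared. VARS, a tRNA synthetase gene that every cell needs, had 0 counts against 78, at least 24.4-fold lower against the floor of 3 counts. It lies on chromosome 6 from 31777518 to 31795953, within the major histocompatibility region, where alternate genome sequences can take reads. RPS18, an abundant ribosomal protein gene of the same region chosen after its values were seen, had 20 and 14 counts, so the counts of VARS do not measure its expression reliably.

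The remaining lists did not stand apart, although some did under an alternative, as given at the end of this paragraph. Cholesterol synthesis had a median of 0.28, fatty acid synthesis and lipid storage 0.33, fatty acid oxidation 0.03, heat shock proteins -0.40, NRF2 targets -0.03 and apoptosis regulators -0.08. Interferon-stimulated genes had a median of 0.17, antigen presentation 0.36, targets of NF-kB with cytokines 0.58, Wnt targets 0.26 and the Notch pathway 0.15. Basal cell genes were at 0.44, ABC transporters with drug efflux genes at 0.48, cytochrome P450 with phase II genes at 0.30, and stem-like and lineage plasticity genes at 0.06. The lists that stood apart as higher under an alternative were Notch (CPM minimum of 5, or mean), NF-kB (mean, or GC and length trends removed), Wnt (mean), basal cell genes (CPM minimum of 5), and cholesterol synthesis (GC and length trends removed). Several medians depended on the members used. With a CPM minimum of 5 they were -0.37 for interferon-stimulated genes, 1.07 for antigen presentation, 0.17 for NF-kB, 1.25 for basal cell genes, 0.64 for Notch and -0.17 for cytochrome P450 with phase II genes. Means were -0.40 for fatty acid oxidation, 0.16 for fatty acid synthesis and for apoptosis regulators, 0.65 for Wnt and 0.14 for ABC transporters.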

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

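Tests chosen after the data were seen are scaling without mitochondrially encoded genes, removal of GC and length trends, and gene counts from the authors' CPM. The counts of genes moved by over 1.5 times with 3 choices: a fold limit of 1.5 gave 2748 higher and 3087 lower, a limit of 4 gave 364 and 416, as follows from the limits, and an assumed coefficient of variation of 0.4 left 487 and 630, as follows from the wider interval. The other alternatives gave between 1033 and 1640 higher and between 1398 and 1857 lower. No title gene passed the rule with DESeq2 size factors, total counts or the authors' CPM. Of the 22 lists, 17 stood apart under every alternative computed for them, and 8 other lists stood apart under at least 1. The mean of the TGF-beta and BMP list was -0.0774 against a median of 0.49, and 0.31 without BMPR1B. Of 367 list medians under alternatives, 321 stayed within their counting error, 45 moved with no change of direction in a list that stood apart, and 1, that mean, reversed. Signs also changed in lists that did not stand apart, which are not counted as reversed. Interferon-stimulated genes went from 0.17 to -0.37 with a CPM minimum of 5. Cytochrome P450 with phase II genes went from 0.30 to -0.06 without a CPM minimum. Of 584 alternative values for named genes, 566 stayed within their counting interval, 18 moved and 0 reversed. Most named genes were picked for passing the rule, so the choice of genes left little room for a reversal. Other scalings moved named genes by at most 0.042. Restriction to protein-coding genes changed nothing, as the table holds no other kind. A prior count of 0.5 left the same 22 lists apart and moved low-count genes further from 0, as MAF from -6.69 to -7.09 and AKR1C3 from 3.07 to 3.45. No paired analysis was possible because each group has 1 library, and no library could be left out. Depth limits genes near 1 CPM, where a few counts set the ratio.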

Other observations

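The pathway description and the tests of abundant genes, luminal share, androgen-repressed genes, poly(A) selection and paralogs were chosen only after their results were seen. Both tests of GC content and length and the test of targets of hypoxia-inducible factor (HIF) were set before their own results were seen, though after the patterns. All genes named in the next paragraphs outside the rule were likewise chosen after their values were seen.

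Pathways of the deposited annotation with at least 10 measured members numbered 252. Of these, 29 had a median in the lowest 2.5% of matched random lists and 53 in the highest. If genes varied independently, 6.3 would be expected in each. Pathways share genes, and genes of a pathway can vary together, so these are not separate results. Ribosome biogenesis had a median of -0.56 over 70 members with 14 lower and 2 higher, the spliceosome -0.32 over 122 members with 21 lower and 4 higher, and the proteasome -0.46 over 38 members with 4 lower and 0 higher. DKC1, a pseudouridine synthase gene, was lower at -1.52, and POP1, an RNase P and MRP subunit gene, at -2.59. One-carbon metabolism through folate had a median of -0.77 over 16 members with 7 lower and 1 higher, with MTHFD1 at -1.97, the thymidylate synthase gene TYMS at -1.76 and SHMT1 at -1.26. The median of the ribosome pathway was not low, at 0.05 over 128 members, although 15 were lower and 1 higher. Those past the rule included genes of mitochondrial ribosomal proteins, such as MRPL15, MRPS17 and MRPL23, as well as RPL22L1 and RPS4Y1.

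ECM-receptor interaction had a median of 0.67 over 43 members with 15 higher and 6 lower, where COL1A1 stood at 1.46 and the syndecan gene SDC4 at 1.41, while LAMA1 was lower at -3.26 and RELN at -2.37. MAPK signalling had a median of 0.39 over 181 members with 39 higher and 10 lower, including the kinase gene MKNK2 at 3.13. The PI3K-Akt pathway, with a wider membership than the list in the report, had a median of 0.23 over 169 members, in the highest 2.5%, with 39 higher and 17 lower. Of 40 pathways named as signalling pathways 15 lay in that tail and 0 in the lowest, though these pathways share genes. FoxO at 0.32, Ras at 0.35 and HIF-1 at 0.28 were among the 15, and p53 at -0.03, Notch at 0.11 and Wnt at 0.14 were not. Glycolysis and gluconeogenesis had a median of 0.24 over 45 members, 15 higher and 5 lower, at percentile 96.1, outside that tail and far below the 1.94 of the list in the report. Circadian rhythm genes had a median of 0.45 over 22 members with 8 higher and 2 lower. Of these, BHLHE40, which is also induced by hypoxia, was at 3.83, PER1 at 2.65, NR1D1 at 2.64 and CRY2 at 1.96. In the list for fatty acid synthesis and lipid storage, which did not stand apart, 6 of 22 members were higher and 5 lower.

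Glycolysis and hypoxia genes were higher and mitochondrially encoded genes lower in ENZ. A few abundant genes taking counts would move all other genes by 1 factor and so could not part this list from the rest. Its median lay 1.96 above that of all genes, with a lower quartile of 1.18, which restates that the list stood apart and is no separate test. The 20 most counted genes took 12.4% of counts in ENZ and 12.1% in ENZ-con, which argues against that cause for this list. The list median was 2.09 after removal of GC and length trends, which argues against those trends as the whole cause. A HIF-type response in the ENZ culture is a candidate explanation. The 22 HIF targets outside glycolysis had a median of 1.19, above all 10000 random lists, with 12 higher, such as CXCR4 at 3.71, and 1 lower. The first list already held hypoxia genes such as CA9 and ANKRD37, so these targets are not separate support for such a response. Whether such a response came from the drug, from cell density or from oxygen supply in 1 culture was not tested, nor was the lower level of mitochondrially encoded genes.

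Androgen-responsive genes were lower while KLK3 was within 2-fold. A lower share of prostate luminal cells would lower the identity genes of that lineage by about as much, but 9 of them had a median of -0.18 (quartiles -0.92 and 0.08), with 0 past the rule, although FOXA1 stood at -0.92, FOLH1 at -0.96 and HOXB13 just short of 2-fold lower. Removal of GC and length trends left the median of the androgen-responsive genes at -1.58, which argues against these trends as the whole cause. Within that list, KLK2 at -0.75, TMPRSS2 at -0.55 and KLK4 at 0.59 stayed within 2-fold, unlike FKBP5 at -3.28. Of 7 measured genes that androgen represses 2 were higher and 3 lower, which decides nothing about the cause.

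Replication-dependent histone mRNAs were higher while replication genes were lower. These mRNAs mostly lack a poly(A) tail, so incomplete poly(A) selection could raise them, and would raise genes with short transcripts alone as much as those that also have a longer annotated transcript. In pooled counts, 11 genes with a transcript over 700 bases went from 3026 counts in ENZ-con to 12254 in ENZ, a pooled log2 ratio of 2.11, against 0.69 for the other 11, a difference of 1.42. This does not exclude incomplete selection, since few abundant genes carry the pools and members go both ways, with HIST1H2BK at -0.35. Reads exchanged among these genes alone would leave the summed count level, but the sum over 22 genes was higher by 1.66, from 5251 to 15625 counts, which argues against such exchange as the whole cause. No biological explanation was tested, and polyadenylated histone transcripts in slowly dividing cells stay open.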
